A study of Mus musculus with 8 samples.

How the data were processed

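Gene expression was measured on 8 Affymetrix MoGene 2.1 ST arrays, which carry probes for mouse transcripts of every biotype. Per the labels, the RNA was total RNA of oocytes from female ICR mice aged 8 weeks that were kept on a diet free of phyto-oestrogens, with 4 arrays of untreated animals (control) and 4 of animals given bisphenol S (BPS) at 0.1 ng per g body weight per day. BPS was given by oral gavage for 7 days in 50% glycerol with 0.1% DMSO, per the labels' protocols. The protocols name no vehicle treatment for the control arrays, and they describe the collection of ovaries while the tissue field and the extraction protocol name oocytes. RNA with an integrity number above 8 was used, per the labels' protocols.

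Per the file headers, the authors summarised each probe set at gene level with RMA and annotated it with NetAffx release 36 on mm10, and the submitters' processing notes name the Transcriptome Analysis Console. Both deposited tables hold log2 signals with 2 decimals, and all 8 signal columns of the authors' workbook equalled a column of the series matrix value for value. The workbook values could therefore not act as an alternative source. The workbook also holds the authors' group averages in log2, standard deviations, a signed fold (control over treated, per the file headers), p-values and FDR-adjusted p-values; the authors' test is not given in the sources used here, and 4 of the p-values are written with a decimal comma. Array medians lay between 4.15 and 4.21 and upper quartiles between 4.60 and 4.81 log2 units, so the deposited distributions were close but not identical. Whether a further scaling was applied after RMA is not given in the sources used here. Correlations between arrays ran from 0.941 to 0.982, and no array repeated another.

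All 34472 probe sets were tested. Of these, 29971 carried 1 gene symbol, 1902 several and 2599 none, and genes were named only from probe sets with 1 symbol. Symbols were matched to the GRCm38.p6 gene table by accession for 23010 probe sets, by symbol for 4034 and by synonym for 145, and 2782 were not matched. Coordinates are from that table and are on the assembly the array annotation uses. 962 probe sets share all 8 values with another probe set and were kept. The background level was 4.53, the 95th percentile of the mean signal of 1408 Y-linked, olfactory and vomeronasal receptor probe sets, and 10236 probe sets lay above it. The number of arrays limits the precision of every value.

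The comparison was BPS minus control, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 without covariates, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. A relaxed count took probe sets with an unadjusted p under 0.05 and a fold of at least 1.5. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, using the brightest probe set per gene symbol and lists with at least 3 measured members. Camera with an estimated correlation and fry were run beside it. A p "adjusted over the list alone" took the members of 1 list as the tested set. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

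The named genes were set by a rule fixed before the data were examined, as were the gene lists, the test and most alternatives. Part 1 took up to 12 single-symbol probe sets per direction past the adjusted threshold, and filled the 12 by unadjusted p from probe sets under 0.05 with at least 1.5-fold and no overlap between groups, then from those without the fold minimum. In this part predicted and RIKEN symbols, microRNAs, small nucleolar RNAs and olfactory and vomeronasal receptors were counted as classes, with at most 2 of them named per direction. 5S ribosomal RNA symbols are not among these classes. Part 2 took the 2 members of each list with the smallest unadjusted p. Part 3 named Gdf9, Zp3, Ddx4, Amh, Fshr, Cyp19a1, Cyp17a1, Star, Esr1, Esr2, Sirt1, Cyp1a1 and Cyp1b1 in any case. Some genes that the rule picks are not reported here.

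The titles number the arrays 1 to 4 in both groups. The deviations of same-numbered arrays from their group means, over probe sets above the median level, correlated at 0.519, 0.383, 0.173 and 0.362. By the rule set for this check, a correlation over 0.1 in every pair, the numbers were treated as pairing the samples. The pairing is at most a hint from the data, since the labels do not say what the numbers share. Arrays of other numbers also correlated, control 1 with BPS 2 (0.453) and control 2 with BPS 1 (0.305). Control 3 correlated more with BPS 4 (0.437) than with BPS 3, and control 4 more with BPS 3 (0.493) than with BPS 4. Same-numbered arrays thus did not consistently correlate more than other arrays of the same series of names. The check therefore gives no support for pairing by number beyond that series, which is described below. Values with the replicate block are given where they change a call, and those with the array-series block where it alone does.

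In the authors' workbook the arrays carry names with either a number or a letter, 2 of each per group. By their values, the number-named arrays are replicates 1 and 2 of both groups and the letter-named arrays replicates 3 and 4. Deviations of arrays of different groups correlated at a median of 0.41 where both names were of the same series and of -0.373 where they were not. What the 2 series stand for is not given in the sources used here. A fit with the series as a block, fits within each series, and the block with quantile normalization were added after the data were seen. The alternatives set beforehand were quantile normalization, median centring, filters on level and annotation, trend and robust variance, array weights, an unmoderated 2-sample test, other fold minimums, the mean of a gene's probe sets in place of the brightest, the replicate block and leaving out each array.

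The procedure was tested on simulated arrays with the variances of these data, with 50 of the 34472 probe sets changed at each of 4 sizes, drawn from the brighter probe sets. At a log2 change of 0.5, 17 of 50 were recovered in the BPS against control comparison, at 1 it was 35, at 1.5 it was 45 and at 2 it was 49, with 12 false calls. With a simulated series difference and the series as a block it was 15, 33, 45 and 48, with 7 false calls. The simulated noise was drawn independently for each array and probe set. The deviations of the real arrays followed the series of names, so these rates need not hold for them.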

Results

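The data comprised 8 oocyte arrays, 4 from control mice and 4 from mice given bisphenol S (BPS), a bisphenol A analogue used in plastics and thermal paper. The comparison asked which transcripts differed after 7 days at a low dose, 0.1 ng per g body weight per day. Signals are log2 RMA values, differences are BPS minus control on that scale, and errors are SD over n = 4 arrays for a group or SE for a difference.

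Oocyte genes had high signals in both groups. Of 40 measured oocyte genes, 39 lay above the background level of 4.53, with a median level of 9.42. Zp3, a protein of the zona pellucida, stood at 10.95 ± 0.07 (SD, n = 4) in control and 10.98 ± 0.03 (SD, n = 4) in BPS arrays, and Gdf9, an oocyte growth factor, at 9.86 ± 0.08 and 9.82 ± 0.04. Ddx4, a germ cell RNA helicase, stood at 6.28 ± 0.23 and 6.44 ± 0.18. Markers of somatic cells were mostly at background. None of 13 theca and stroma genes, none of 7 erythroid genes and 5 of 17 granulosa cell genes lay above it, and the median levels of these lists were 4.14, 4.02 and 4.26. Amh and Fshr, granulosa cell genes, and Cyp19a1, the aromatase gene, lay below it in both groups. Principal components separated the arrays by group and by the series of their names in the authors' deposited table.

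**Figure D1:**
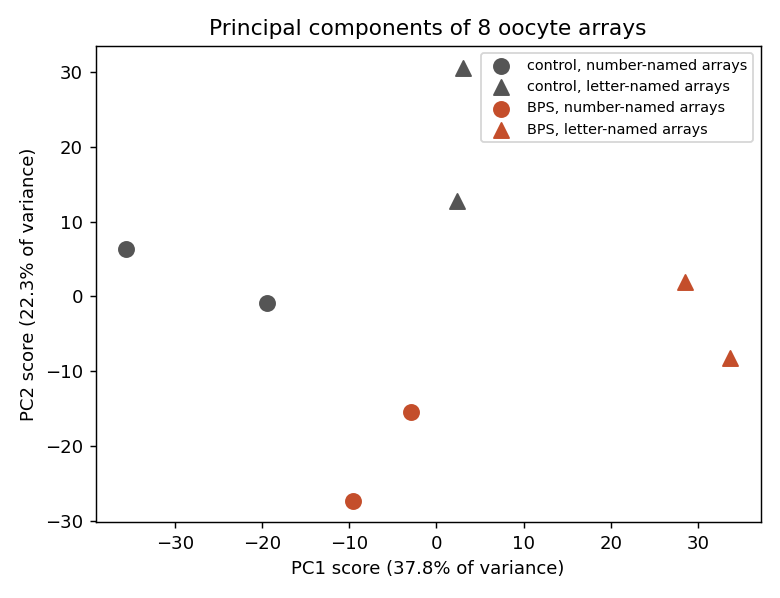
First and second principal component scores (PC1, 37.8% of the variance, and PC2, 22.3%) of the 8 arrays, with colour for the group and shape for the number or letter series of the array names. Within each series the BPS arrays lie at higher PC1 and lower PC2 scores than the control arrays.

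3 probe sets passed the adjusted threshold, 2 higher and 1 lower in BPS. Prl8a2, a member of the prolactin family, rose from 4.91 ± 0.09 to 6.32 ± 0.28 (SD, n = 4), a 2.65-fold difference (log2 1.41 ± 0.13 SE, limma adjusted p = 0.0498). G3bp1, which codes for a nucleating protein of stress granules, rose from 5.48 ± 0.05 to 6.01 ± 0.05 (SD, n = 4), with a log2 difference of 0.53 ± 0.05 (SE, limma adjusted p = 0.0498). Gm25205, a predicted small nuclear RNA gene, fell from 6.18 ± 0.09 to 4.96 ± 0.17 (SD, n = 4; log2 difference -1.23 ± 0.09 SE, limma adjusted p = 0.0222). The 4 BPS values of each lay outside the range of the 4 control values. On GRCm38.p6 Prl8a2 spans 27345673 to 27354216 of chromosome 13, G3bp1 spans 55469657 to 55500888 of chromosome 11 and Gm25205 spans 64413648 to 64413750 of chromosome 6. Within the number-named and the letter-named arrays the differences were 1.39 and 1.42 for Prl8a2, 0.49 and 0.57 for G3bp1, and -1.14 and -1.32 for Gm25205. When 1 array was left out, the adjusted p ran from 0.0477 to 0.337 for Prl8a2, from 0.107 to 0.337 for G3bp1 and from 0.0332 to 0.196 for Gm25205, and the count of 3 became 0 without any 1 of the 4 control arrays or BPS replicate 4, 2 without BPS replicate 1 or 2, and 3 without BPS replicate 3. After quantile normalization 0 probe sets passed, with 3753 at an unadjusted p under 0.05 in limma. Among probe sets above the median level or above background G3bp1 did not pass (limma adjusted p = 0.119 and 0.164). Of 9 alternatives set beforehand besides leaving out arrays, Prl8a2 passed in 5, G3bp1 in 3 and Gm25205 in 6. The 9 include quantile normalization, the level filters just given and the replicate block.

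**Figure D2:**
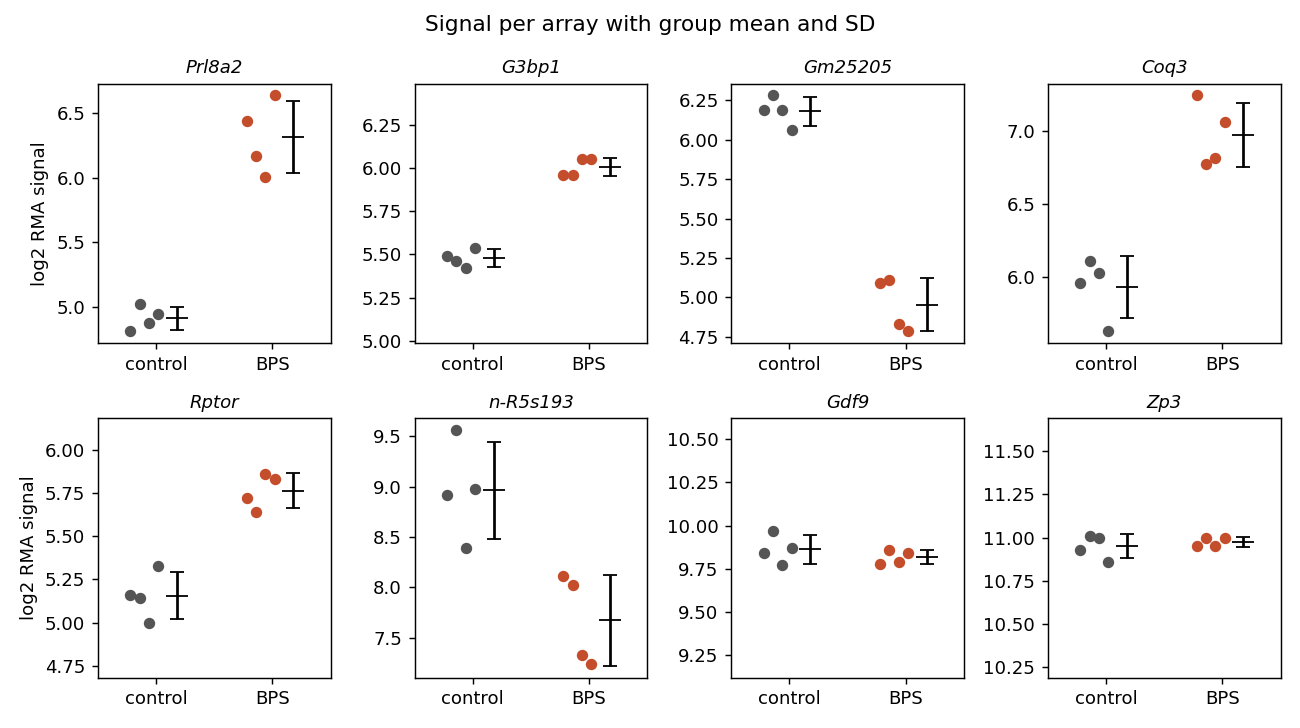
log2 RMA signal of each array (points) with group mean and SD (bars) for 8 genes, control against BPS, each panel on its own axis. Prl8a2, G3bp1 and Gm25205 passed the adjusted threshold, Coq3, Rptor and n-R5s193 did not, and Gdf9 and Zp3 differed by -0.05 and 0.03.

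Blocking changed the count of calls. With the replicate numbers as a block, 685 probe sets passed at an adjusted p under 0.05, 548 higher and 137 lower in BPS, and with the series of array names as a block, added after the data were seen, 1195 passed, 958 higher (80.2%) and 237 lower. After quantile normalization the array-series block gave 611, 345 higher (56.5%) and 266 lower. All 3 probe sets named above passed with either block, and 553 probe sets passed with both. The blocks are not separate adjustments, since each replicate number lies within 1 series and the replicate block also takes out the series difference. Passing both is therefore not independent support. The count of 1195 ran from 279 to 1229 when 1 array was left out, with 279 and 1229 without either number-named control array, 567 and 315 without either letter-named one, 652 and 508 without either number-named BPS array and 482 and 345 without either letter-named one. The authors' deposited table held 0 probe sets with an FDR under 0.05, with a smallest FDR of 0.165, and 1831 with a p under 0.05, of which 1365 were higher and 466 lower in BPS.

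At the relaxed threshold, 517 probe sets differed by at least 1.5-fold with an unadjusted p under 0.05, 389 of them higher (75.2%) and 128 lower in BPS. After quantile normalization of the same values there were 427, with 189 higher (44.3%) and 238 lower, and after median centring 483, with 337 higher (69.8%) and 146 lower. After quantile normalization 315 of the 517 still met the threshold. The 389 higher probe sets became 219 without control replicate 1, 233 without BPS replicate 4 and 615 without BPS replicate 1. The median difference over probe sets above background was 0.12 with the deposited values, 0.10 after median centring and 0.00 after quantile normalization, so differences of genes are to be read against that shift. The authors' deposited table held 327 such probe sets, 250 higher and 77 lower, of which 287 were among the 517. In 2001 probe sets (5.80%) the 4 BPS values did not overlap the 4 control values, against 2.86% by chance if all 8 arrays are exchangeable.

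**Figure D3:**
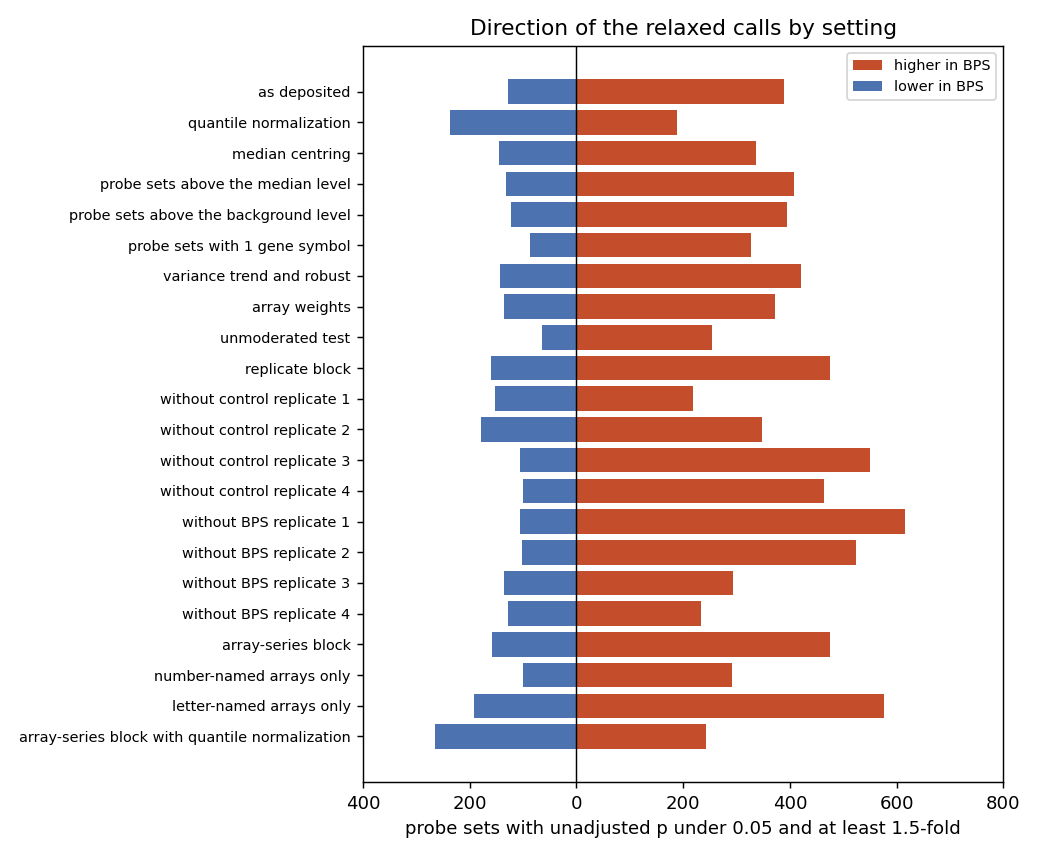
Number of probe sets with an unadjusted p under 0.05 and at least 1.5-fold, higher (right) or lower (left) in BPS, under each setting. The share of higher probe sets was 75.2% with the deposited values, 69.8% after median centring and 44.3% after quantile normalization.

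The next 10 genes that the naming rule took on the higher side did not pass the adjusted threshold without a block. Coq3, a methyltransferase of coenzyme Q synthesis, differed by 1.04 ± 0.14 (SE), and Fkbp8, an anti-apoptotic chaperone of mitochondria, by 0.69 ± 0.09. Rptor, the raptor subunit of the mTORC1 kinase, differed by 0.61 ± 0.08 and Kars, the lysyl-tRNA synthetase gene, by 0.69 ± 0.10. Brip1, a helicase that binds BRCA1, differed by 0.65 ± 0.09, Exoc1 of the exocyst by 0.65 ± 0.08 and Wdr73 by 0.62 ± 0.08. Ceacam10 differed by 1.15 ± 0.17, and the predicted symbols LOC101055953 and Gm24103 by 1.04 and 0.87. Their adjusted p lay between 0.157 and 0.159 in limma without a block, and with the replicate block between 0.0356 and 0.0495.

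On the lower side the genes that completed the 12 did not pass without a block. 3 were 5S ribosomal RNA gene copies, n-R5s56 with -1.70 ± 0.49 (SE), n-R5s193 with -1.29 ± 0.29 and n-R5s96 with -0.43 ± 0.08. Whether their probe sets separate the copies was not analysed here, nor was it for small nuclear RNA genes such as Gm25205 or for histone genes. Gm25811, a predicted pseudogene, differed by -0.97, Clca4a, of the chloride channel accessory family, by -0.66, Wipi2, a phosphoinositide-binding protein of autophagosome formation, by -0.57 and Ugt8a, a ceramide galactosyltransferase, by -0.56. These 7 passed with the replicate block, at adjusted p between 0.0356 and 0.0483. Defb3 (-0.36), Ube2dnl1 (-0.30) and Lmx1b (-0.22) lay below background in mean signal and did not pass with it. Defb3 and Ube2dnl1 passed with the array-series block (adjusted p = 0.0459 and 0.0447).

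Of 36 gene lists, 4 differed from the other genes at an adjusted p under 0.05 with camera's preset correlation. The 80 genes of the nuclear respiratory chain had a median difference of 0.14, with 69 positive and 11 negative members (adjusted p = 0.00206), and the adjusted p was 0.988 with an estimated correlation. Ndufs8 and Ndufa9, subunits of complex I, differed by 0.56 ± 0.18 and 0.31 ± 0.09 (SE), and Ndufs8 passed with the array-series block (adjusted p = 0.0229). The 18 meiotic prophase genes had a median of 0.11 with 17 positive members (adjusted p = 0.0292, and 0.988 with an estimated correlation). Of these 18, 10 lay above background. Hormad1, a protein of the unsynapsed chromosome axis, lay below background in mean signal and differed by 0.29 ± 0.09 (SE). The 1396 olfactory and vomeronasal receptor genes (median -0.01, adjusted p = 0.00206, and 0.988 with an estimated correlation) and 501 microRNA genes (median -0.01, adjusted p = 0.0292, and 0.559 with an estimated correlation) lay below the other genes. Only 69 of the receptor and 77 of the microRNA genes lay above background, a level that receptor probe sets help to set. Probe sets above background had a median difference of 0.12, so a place below the other genes is not by itself a fall. Among genes above background the medians were -0.04 and -0.02 (camera adjusted p = 1.79e-05 and 0.000432). Without a block no member of any of the 4 passed over all probe sets or adjusted over the list alone. With the array-series block 7 respiratory chain and 1 meiotic prophase genes passed as higher, 10 receptor genes as higher and 10 as lower, and 11 microRNA genes as higher and 6 as lower. With the replicate block it was 5 and 9 receptor genes and 7 and 5 microRNA genes, and none of the other lists. After quantile normalization the adjusted p of the 4 lists were 0.091, 0.253, 0.442 and 0.557 in the same order. Among probe sets above the median level or above background the 2 higher lists did not pass, with adjusted p of 0.12 and 0.296 for the respiratory chain and 0.541 and 0.922 for meiotic prophase. Against 10000 random lists of like signal level the median of the respiratory chain list lay at percentile 99.8 and that of meiotic prophase at 93. The medians of the receptor and microRNA lists lay at percentile 0. The random lists were drawn gene by gene, so they lack the correlation between members, estimated at 0.365 for the respiratory chain. A percentile therefore does not measure the spread between arrays. The respiratory chain median was 0.09 without control replicate 1 or BPS replicate 4. Without BPS replicate 4 the adjusted p of the respiratory chain list was 0.294. The meiotic prophase list did not pass without control replicate 2 (0.105) or 4 (0.143) or BPS replicate 3 (0.0715) or 4 (0.237). The receptor list did not pass without control replicate 2 (0.0538) or BPS replicate 3 (0.447), and the microRNA list not without control replicate 1 (0.0839) or 2 (0.105) or BPS replicate 3 (0.447) or 4 (0.179). The count of 4 lists became 1 without control replicate 2, BPS replicate 3 or BPS replicate 4.

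**Figure D4:**
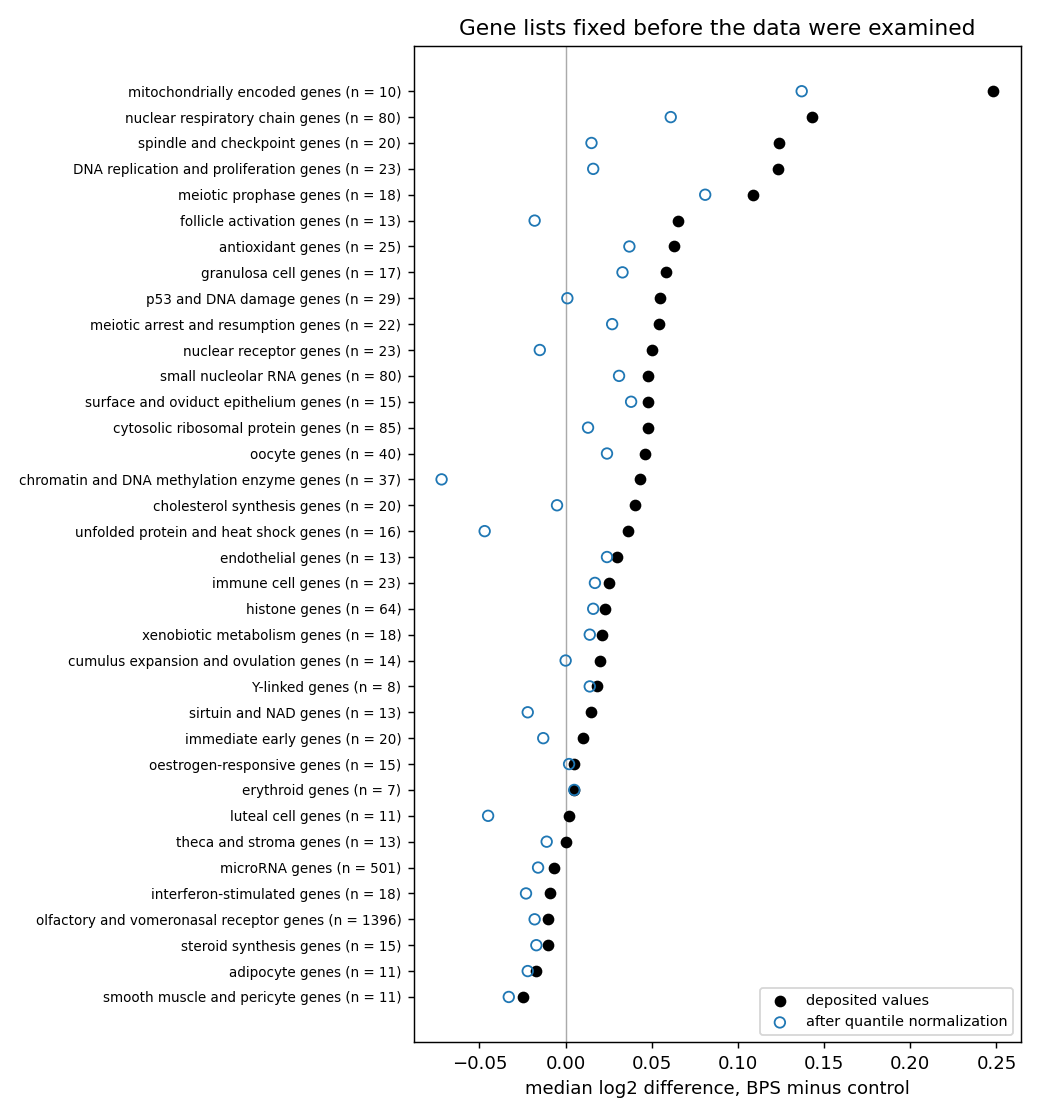
Median log2 difference, BPS minus control, of each gene list with its number of measured genes, from the deposited values (filled) and after quantile normalization (open). The nuclear respiratory chain list moved from 0.14 to 0.06, the spindle and checkpoint list from 0.12 to 0.02 and the follicle activation list from 0.07 to -0.02.

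Without a block no member of the other 32 lists passed over all probe sets, and 6 genes passed when adjusted over the list alone, all higher in BPS. The 40 oocyte genes had a median of 0.05. Obox5, an oocyte homeobox gene, differed by 0.59 ± 0.12 (SE) and passed over the list alone, and Zar1, a maternal-effect gene, differed by -0.38 ± 0.14. Both passed with the array-series block (adjusted p = 0.0405 and 0.0299). Slc18a2, a monoamine transporter gene listed with granulosa cells, differed by 0.55 ± 0.09 and also passed over its list alone and with the replicate block (adjusted p = 0.0485), while the list median was 0.06 and Gata4 differed by 0.23. In meiotic arrest and resumption (22 genes, median 0.05), Wee1, a kinase that inhibits CDK1, differed by 0.61 ± 0.11 and Fbxo43, the EMI2 inhibitor of the anaphase-promoting complex, by 0.32 ± 0.06, and both passed over the list alone. Wee1 also passed with the replicate block (adjusted p = 0.0495) and Fbxo43 with the array-series block (adjusted p = 0.0239). In follicle activation (13 genes, median 0.07, and -0.02 after quantile normalization) Rptor passed over the list alone and Akt1, a survival kinase, differed by 0.29 ± 0.09. Hist1h2af, a histone H2A gene, differed by 1.08 ± 0.21 and passed over the histone list alone (64 genes, median 0.02) and with the array-series block (adjusted p = 0.0199). Hist1h2bp differed by 0.48 ± 0.17 and passed with the replicate block (adjusted p = 0.0419). After quantile normalization the array-series block no longer called Obox5 (adjusted p = 0.107), Zar1 (0.0708), Slc18a2 (0.0794), Wee1 (0.105), Fbxo43 (0.141), Ndufs8 (0.0699), Ifit3 (0.0768), Brip1 (0.068), Defb3 (0.0533) or Ube2dnl1 (0.0631).

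Genes of cell division and chromatin had small positive medians, which were near 0 or negative after quantile normalization. Spindle and checkpoint genes (20, median 0.12, and 0.02 after quantile normalization) included Bub1, a checkpoint kinase, with 0.48 ± 0.13 (SE), and Plk4, the kinase of centriole duplication, with 0.35 ± 0.10. DNA replication and proliferation genes (23, median 0.12, and 0.02 after quantile normalization) included Mcm3 with 0.19 and Tyms with 0.13, which were 0.02 and -0.03 after it. Chromatin and DNA methylation enzyme genes (37) had a median of 0.04 and -0.07 after quantile normalization. In that list Tet1 differed by 0.14 and Dnmt3l by 0.11, the latter -0.05 after quantile normalization. P53 and DNA damage genes (29, median 0.06, and 0.00 after quantile normalization) included Polk, a translesion polymerase, with 0.67 ± 0.27 and an adjusted p of 0.0473 with the replicate block, and Ccng1 with 0.31 ± 0.12.

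Endocrine and xenobiotic genes did not pass in limma without a block, and many lay at background. Above it were 5 of 15 steroid synthesis, 2 of 15 oestrogen-responsive and 2 of 18 xenobiotic metabolism genes. Esr2, Wnt4, Cyp17a1, Star, Cyp19a1, Mvd, Cyp1a1, Cyp1b1, Ephx1, Amh and Fshr lay below background in mean signal. Small differences of such genes do not show that they were unchanged. Esr1 and Esr2, the oestrogen receptors, differed by 0.05 ± 0.12 (SE) and 0.19 ± 0.10, and Esr1 was -0.07 after quantile normalization. The 23 nuclear receptor genes had a median of 0.05, and of -0.02 after quantile normalization, with Pparg at 0.53 ± 0.15 and Thra at 0.18 ± 0.06, and the 15 oestrogen-responsive genes a median of 0.01, with Wnt4 at 0.18 and Ctsd at -0.14. In steroid synthesis (15 genes, median -0.01), Cyp17a1, the 17-hydroxylase, differed by -0.25 ± 0.10, Star, the cholesterol carrier, by -0.08 ± 0.08, Cyp19a1 by 0.02 ± 0.08 and Por by 0.15 ± 0.09. Por was -0.01 after quantile normalization. Sqle, an enzyme of cholesterol synthesis, differed by -0.33 ± 0.09 and Mvd by 0.14, in a list of 20 with a median of 0.04, and of -0.01 after quantile normalization. In the 18 xenobiotic metabolism genes (median 0.02), Cyp1a1 and Cyp1b1, targets of the aryl hydrocarbon receptor, differed by -0.18 ± 0.16 and -0.07 ± 0.07, Ephx1 by 0.21 and Cyp3a11, below background in mean signal, by 0.45 ± 0.18 with an adjusted p of 0.0368 under the replicate block. Amh differed by 0.04 ± 0.08 and Fshr by 0.06 ± 0.06. Sirt1, a deacetylase, did not differ in mean (0.00 ± 0.08), and in the 13 sirtuin and NAD genes (median 0.02, and -0.02 after quantile normalization) Nmnat2 differed by 0.40 and Sirt7 by 0.23.

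Genes of stress and mitochondria gave further values that did not pass without a block. The 10 measured mitochondrially encoded genes had a median of 0.25, which was 0.01 without control replicate 1 and 0.14 after quantile normalization, with ND1 at 0.33 ± 0.12 (SE) and ND6 at 0.14. The 25 antioxidant genes had a median of 0.06, with Txn1, thioredoxin, at 0.43 ± 0.18 (adjusted p = 0.0473 with the replicate block) and Sod2 at 0.13. Interferon-stimulated genes (18, median -0.01) included Ifit3 with -0.73 ± 0.25 and Mx2, below background in mean signal, with -0.22 ± 0.10, which both passed with the array-series block (adjusted p = 0.0489 and 0.0428). Unfolded protein and heat shock genes (16, median 0.04, and -0.05 after quantile normalization) included Calr with -0.21 and Herpud1 with 0.12, and immediate early genes (20, median 0.01, and -0.01 after quantile normalization) included Klf2 with -0.13 and Nr4a3 with 0.09. Cytosolic ribosomal protein genes (85, median 0.05) included Rpl10l, a retrogene copy of Rpl10, with 0.80 ± 0.22 and an adjusted p of 0.0492 with the replicate block, and Rps24 with 0.80 ± 0.24.

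Lists of other cell types lay near background and had medians near 0. These were theca and stroma (0.00, with Col3a1 at -0.13), luteal (11 genes, 0.00, and -0.05 after quantile normalization, with Prlr at 0.16 and Sfrp4 at -0.18), immune (23 genes, 0.03, with Csf1r at 0.09 and Lyz2 at -0.19) and erythroid genes (0.01, with Epb42 at 0.39 and Slc4a1 at 0.06). Endothelial genes (13, 0.03) included Pecam1 at 0.19 and Flt1 at -0.10, smooth muscle and pericyte genes (11, -0.03) Acta2 at 0.26 and Cnn1 at 0.29, and surface and oviduct epithelium genes (15, 0.05) Muc16 at 0.12 and Krt18 at 0.12. Adipocyte genes (11, -0.02) included Pparg and Ucp1 at -0.15, and cumulus expansion and ovulation genes (14, 0.02) Areg at 0.11 and Vcan at 0.08. Among technical classes, 8 Y-linked genes had a median of 0.02, with Sry at -0.19 and Zfy2 at 0.07, and 80 small nucleolar RNA genes a median of 0.05, with Snord110 at 0.21 and Snord47 at 0.31. Olfr1463 and Olfr310 differed by 1.23 ± 0.18 (SE) and -0.52 ± 0.09 and passed with the array-series block (adjusted p = 0.0201 and 0.0282). Mir5099 differed by 0.60 ± 0.13 with an adjusted p of 0.0478 under the replicate block, and Mir759 by -0.25 ± 0.06. In 10 of the 36 lists the median, the mean and the camera direction did not share a sign, among them histone genes (median 0.02, mean 0.11, lower than other genes in camera). No list passed fry's test of whether the genes of a list move, on balance, 1 way, whose smallest adjusted p was 0.168. In fry's test of change in either direction 6 passed, meiotic arrest and resumption (adjusted p = 0.0117), spindle and checkpoint (0.021), luteal (0.0291), follicle activation (0.0314), epithelium (0.0492) and meiotic prophase genes (0.0498). Neither test compares a list with other genes.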

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

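In 23 of 282 groups of 4 values (of named genes and of list means), 1 array lay far from the other 3, where chance gives about 1 in 20. Among named genes on BPS arrays these were Gm24103 in replicate 3 (6.21, others 5.73 to 5.80), Ugt8a in replicate 2 (4.38, others 4.20 to 4.22), Epb42 in replicate 3 (5.29, others 4.34 to 4.50), Pparg in replicate 2 (6.09, others 6.25 to 6.27), Ndufa9 in replicate 4 (8.25, others 7.95 to 8.00), Klf2 in replicate 3 (3.91, others 3.78 to 3.80), Rps24 in replicate 4 (5.88, others 5.37 to 5.43) and Olfr310 in replicate 4 (4.15, others 4.47 to 4.50). On control arrays they were Gm24103 in replicate 2 (4.88, others 5.03 to 5.05), Cnn1 in replicate 1 (4.27, others 4.68 to 4.75), Sod2 in replicate 3 (4.57, others 4.49 to 4.50), Mir759 in replicate 1 (4.04, others 4.26 to 4.27), Cyp19a1 in replicate 2 (4.40, others 4.17 to 4.19) and Sirt1 in replicate 4 (7.86, others 7.61 to 7.65).

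Among list means, control replicate 4 stood apart for oocyte genes (8.73, others 8.90 to 8.92) and olfactory and vomeronasal receptor genes (4.03), control replicate 1 for nuclear receptor genes (4.53) and DNA replication genes (6.24), and control replicate 3 for meiotic prophase genes (5.43, others 5.27 to 5.28). BPS replicate 3 stood apart for erythroid (4.19), smooth muscle and pericyte (4.57) and cumulus expansion genes (4.11), and BPS replicate 1 for immune cell genes (4.18).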

How the results depend on the processing

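The array-series fits were chosen after the data were seen, and the other alternatives before. The count of 3 probe sets past the adjusted threshold was 0 after quantile normalization, with trend and robust variance and with the unmoderated test, 1 after median centring, 0 to 3 in leave-one-out fits and 6 genes when adjusted over each list alone. It was 685 with the replicate block, 1195 with the array-series block, 611 with that block and quantile normalization, and 0 within the number-named or the letter-named arrays, where 2 arrays per group remain. The relaxed count of 517 was 319 with the unmoderated test, 61 at 2-fold, 3827 without a fold minimum and 361 to 720 in leave-one-out fits. The 4 lists became 0 after quantile normalization, with the array-series block and quantile normalization, with an estimated correlation and with fry, 2 among probe sets above the median or above background (those lost are the higher lists), 1 within the number-named arrays and 1 to 5 in leave-one-out fits. Beyond the fewer probe sets, lists or arrays that some settings leave, the cause was not tested.

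Of 2143 values of the 105 named genes under alternatives, 2128 kept their direction. The others, each not past the threshold in either setting, were Por (-0.009), Dnmt3l (-0.052), Tyms (-0.033), Ddx4 (-0.008) and Esr1 (-0.066) after quantile normalization, with or without the array-series block, and in leave-one-out fits Amh (-0.012 to 0.075), Cyp19a1 (-0.011 to 0.086) and Esr1 (-0.032 to 0.123). Prl8a2, G3bp1 and Gm25205 kept their direction in every setting run, at 1.27 to 1.51, 0.35 to 0.57 and -1.34 to -1.14. The array-weights fit, the limit to 1 gene symbol and, for lists, the mean of a gene's probe sets moved none of the 3 counts by over 1.5 times. The workbook, whose signals are identical, gave no separate values, and the unmoderated test gives none for lists. Of the list medians under alternatives, 37 moved by more than the spread between arrays. Among lists not called, 7 medians took the opposite sign after quantile normalization and 3 after median centring, and among those called, the microRNA median did within the number-named arrays (0.005). Values under 0.005 were given no sign. The replicate block changed no list call and, beyond those given in the report, no call of a named gene. The array-series block brought 36 more named genes past the threshold, of which 26 also passed with that block after quantile normalization. Signal over background limits the lists of other cell types and those of steroid synthesis, oestrogen-responsive and xenobiotic metabolism genes.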

Other observations

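The tests below were chosen after the results were seen. 85 protein-coding genes above background differed by at least 1.5-fold and passed the adjusted threshold with either block and with the array-series block after quantile normalization, 79 higher and 6 lower in BPS. With the fold minimum on the quantile-normalized values there were 53, 43 higher and 10 lower. Genes picked from the 85 after their values were seen are given with the difference after quantile normalization in brackets. They included Ogg1, a glycosylase that removes oxidised guanine, with 0.65 (0.565), and Ikbkb, a kinase of NF-kappaB signalling, with 0.65 (0.55). Further ones were U2af1, a splicing factor, with 0.79 (0.70), and Diablo, an antagonist of apoptosis inhibitors, with 0.59 (0.44). Cox10, a cytochrome oxidase assembly factor, differed by 0.80 (0.66). Ogg1, Ikbkb and Diablo thus fell under the 1.5-fold minimum after quantile normalization. On the lower side Scgb2b6, a secretoglobin, differed by -0.88 (-0.99). The control means of Ogg1 (4.42) and U2af1 (4.41) and the BPS mean of Scgb2b6 (4.34) lay under the background level of 4.53. These 6 did not pass without a block, where their adjusted p were 0.224 or more.

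Transcript classes differed in their medians, without passing an exact test over the arrays for the gap given below. Above background, 207 protein-coding probe sets met the relaxed threshold as higher and 14 as lower in BPS, while small nuclear RNA probe sets gave 5 and 22. Median differences were 0.13 for 7601 protein-coding (0.01 after quantile normalization), 0.20 for 259 long non-coding RNA (0.09), -0.17 for 171 small nuclear RNA (-0.27) and -0.31 for 24 probe sets of 5S ribosomal RNA (-0.40). The small nuclear RNA median was -0.07 without control replicate 3, whose median signal of these probe sets was 5.21 against 4.79 to 4.89 in the other controls and 4.79 to 4.93 in the BPS arrays, and -0.14 to -0.20 without any other array. The gap between small nuclear and protein-coding medians was -0.30 (exact permutation p = 0.0571, two-sided, 70 arrangements, where the smallest possible p is 0.0286). With arrangements balanced over the array series it was 0.111 of 36 arrangements, which cannot give a p under 0.0556.

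Without a block, 2 of the 35 splits of the 8 arrays gave as many as 3 probe sets, so chance cannot be excluded. The highest other gave 24, the count of the letter-named against the number-named arrays, which points to a structure of the samples; with the array-series block the BPS comparison gave 1195. For the relaxed count of 517, 3 of the 35 splits gave as many (highest other 721, again the count of letter-named against number-named arrays), and for the 4 lists 14 splits did (highest other 14 lists), so chance cannot be excluded for these either. Nor can it for the 2001 probe sets whose groups did not overlap, since 3 of the 35 splits gave as many (highest other 2922). With the array-series block 18 splits keep the series balanced (real 1195, highest other 0, 1 as large), and with the replicate block 8 splits part all pairs (real 685, highest other 0, 1 as large), too few for a share under 0.05. In these splits the relaxed count was 633 (highest other 197) with the array-series block and 636 (highest other 111) with the replicate block. For the 4 lists the highest others were 16 and 15. The other splits that part the pairs exchange control and BPS arrays within 1 or more numbers.

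The first pattern is the small count of calls without a block beside the large count with one. Deviations within a series correlated at a median of 0.41 between groups. With treatment as a block, 1899 probe sets differed between letter-named and number-named arrays at a limma adjusted p under 0.05. A series difference was thus present, and spread that follows it may account for the low count without a block. Whether the series was a hybridisation batch or a set of animals stays open, as does an effect of BPS on the genes called with a block.

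The second pattern is that most relaxed calls were higher in BPS. Scaling of the arrays may account for the excess. After quantile normalization 44.3% were higher, and after median centring 69.8%. Quantile normalization gives all arrays the same distribution and would take out a general rise of any origin, so the 44.3% cannot single out scaling. A gradient over arrays shared with the array series may also contribute. Of the relaxed calls higher in BPS, 82.0% were higher in the letter series against 72.9% of all probe sets above background, and of those lower in BPS 39.8% were lower in it against 27.1%. Both stay open, as does a change in total RNA with treatment, which was not tested.

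The third pattern is the lower signal of small nuclear RNA, for which chance stays open (exact permutation p = 0.0571). Quantile normalization did not remove the lower median. It was -0.17 before it (exact permutation p = 0.0571) and -0.27 after it (exact permutation p = 0.0286, the smallest that 70 arrangements can give). These arrangements exchange arrays across the array series, and those balanced over the series cannot give a p under 0.0556. The p-values therefore cannot decide against scaling. The small nucleolar RNA median was 0.10 (-0.04 after quantile normalization). Small nuclear RNA differed from it by -0.27 (exact permutation p = 0.0286), by -0.15 without control replicate 4 and by -0.18 without BPS replicate 2. These medians did not fall alike, but this p also ignores the array series, so an equal loss of all small RNAs stays open. A loss of some small RNAs also stays open, since the median difference of 5S ribosomal RNA was negative too. It was -0.20 in the number series and -0.425 in the letter series. The 5S difference was not tested over the arrays, and control replicate 3 again had the highest median signal (5.13). The gap of small nuclear RNA to microRNA was -0.17 (exact permutation p = 0.0286, over the same 70 arrangements), and -0.05 without control replicate 3. The share of control replicate 3 stays open as well, and without it the gap to protein-coding probe sets was -0.21. That gap was -0.13 in the number series and -0.48 in the letter series. Each series holds 2 arrays of each group, so a series difference that is equal in both groups cancels and cannot give the gap. Whether the size of the gap depends on the series stays open with so few arrays. A treatment effect, as a hypothesis, also stays open.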
